A study of Phaeodactylum tricornutum with 6 samples.

How the data were processed

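Libraries made from total RNA of 6 cultures of Phaeodactylum tricornutum, 3 acclimated to 940 and 3 to 20 µmol photons m-2 s-1, were sequenced. Per the labels' protocols, cells grew axenically, optically thin and exponentially in enriched artificial seawater without silica, RNA was taken up in TRIzol and treated to remove DNA, and libraries were made with the TruSeq RNA Library Prep Kit v2 and sequenced on an Illumina MiSeq. That kit does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. The deposited table holds raw read counts per gene, whole numbers that are not normalized. The submitters' processing notes name DESeq2, while the aligner, the counting program, the strand setting and the genome build are not given in the sources used here. How reads shared between near-identical copies were counted is likewise not given there.

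Samples were grouped by the labelled growth condition, and the columns were matched to samples by light level and replicate number. Library totals lay between 7365090 and 8442228 counts. Intervals on counts are 95% intervals that cover counting error only and leave out variation among cultures. PCR copies were not removed by molecular identifiers, so even the counting error can be understated. Of 12178 genes, 777 had 0 counts in every library. Gene symbols came from the gene table of assembly ASM15095v2, used only for names and for the order of neighbouring genes. IDs were matched to locus tags by their shared number, which matched 9377 IDs, and 99.97% of neighbouring matched IDs followed the order of the reference. A symbol was found for 580 IDs, which held 12.6% of the counts, and 567 of these were tested. The 2603 IDs of the EG kind, with 15.9% of the counts, were not matched and have no symbol here.

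The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) of high against low light with TMM scaling and no covariate. Its low count filter, with a minimum count of 10 and a minimum total of 15, left 10629 genes and removed 1549. P-values were adjusted by Benjamini and Hochberg's method and called under 0.05. Standard errors were derived from the fold change and its F statistic. CPM are counts scaled to a common library total with the TMM factors, given with the SD over 3 cultures. On simulated counts with known changes, the test found 2 of 50 genes changed 1.5-fold, 37 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold among 10566 genes in the high against low light comparison. Of 156 genes called there 8 belonged to a further list of 15 genes raised 2-fold and 10 had not been changed, and 0 of 10565 were called when nothing was changed. Only these few genes were changed in the simulation, whereas 59.0% of tested genes were called in the data. The adjusted threshold is looser there, so the simulated rates need not hold for the real comparison.

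Before the data were examined, 30 gene lists were fixed as patterns on symbols and product names. The gene table holds no product names, so lists were matched by symbol alone and 24 had a member. The lists of fatty acid oxidation, storage glucans, plastid-encoded and mitochondrion-encoded genes, retrotransposons and contaminants had none and were not analysed here. The 12 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took the 12 largest increases and 12 largest decreases among called genes with a symbol, at least 10 CPM on average and no overlap of the groups, then 3 of each whatever the name. It added up to 3 called members per tested list by size of change, every tested Lhcx and photoreceptor gene, and the 5 most abundant genes of each group. This gave 67 genes. Other members of the fixed lists are named as examples and were chosen after their values were seen.

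Alternatives fixed beforehand were relative log expression size factors, total count scaling, TMM without the 100 most abundant genes, DESeq2 1.42.0, limma-voom, no low count filter, a minimum of 5 CPM in 3 libraries, thinning to the smallest library, a replicate block and leaving out each library. Leaving out both replicate 1 libraries, and leaving PSAT and CPNE1b out of their lists, were added after seeing the data. The gene silencing lines named in the study's design were not analysed here.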

Results

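Messenger RNA was profiled in the marine diatom Phaeodactylum tricornutum, a unicellular alga with a plastid of secondary origin and fucoxanthin-chlorophyll antennae. Wild type cells of strain CCMP632 had been acclimated to high light (HL, 940 µmol photons m-2 s-1) or low light (LL, 20 µmol photons m-2 s-1), with 3 biologically independent cultures in each group. The count table held 12178 genes in 6 libraries. Library totals were 7365090, 8442228 and 8103787 counts in LL and 7792706, 7715170 and 8355436 in HL, and between 11061 and 11202 genes had at least 1 count. The 100 most abundant genes of a library held 33.0%, 33.5% and 30.8% of its counts in LL and 21.3%, 21.0% and 20.8% in HL. The series concerns how signals from the plastid to the nucleus shape acclimation to light, and HL against LL was the comparison its design implied.

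Acclimation to HL was accompanied by changes in most of the measured transcriptome. The antenna genes Lhcx1, of the stress-related Lhcx group, and Lhcf15 and Lhcf5, of the light-collecting Lhcf group, fell. They were 32.5-fold, 20.8-fold and 20.1-fold lower in HL than in LL, in that order. The heat shock transcription factor genes HSF1, HSF2 and HSF3 fell as well, and so did Tpt3, a member of the triose phosphate translocator family (8.47-fold lower). Among genes that rose were MCM2, a subunit of the replicative helicase (16.03-fold higher), PGK, phosphoglycerate kinase (5.41-fold higher), and the chaperonin CPN60_1 (2.67-fold higher). Each of these named genes moved in the same direction and passed the test under both scalings of the libraries. For genes that rose this adds no support, since total count scaling raises all genes alike. All 3285 genes higher under TMM scaling were also called higher under total count scaling.

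Of 10629 genes tested, 3285 were higher and 2986 lower in HL (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 3367 of these had changed at least 2-fold, 1678 upward and 1689 downward. The 2 groups did not overlap in 66.0% of tested genes, against 10% by chance for 3 libraries against 3. Scaling decided the balance of directions. TMM factors lay between 0.69 and 0.78 in LL and between 1.29 and 1.40 in HL, and scaling by total counts alone raised the median log2 fold change by 0.87, from 0.09 to 0.96. Under that scaling 7233 genes were higher and 1130 lower, so that 86.5% of called genes were higher in place of 52.4%. In all, 4415 genes were called in the same direction under both scalings, 3285 higher and 1130 lower, and 1048 genes called under TMM changed sign. Fold changes below are relative to the TMM scaling unless stated.

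**Figure D1:**
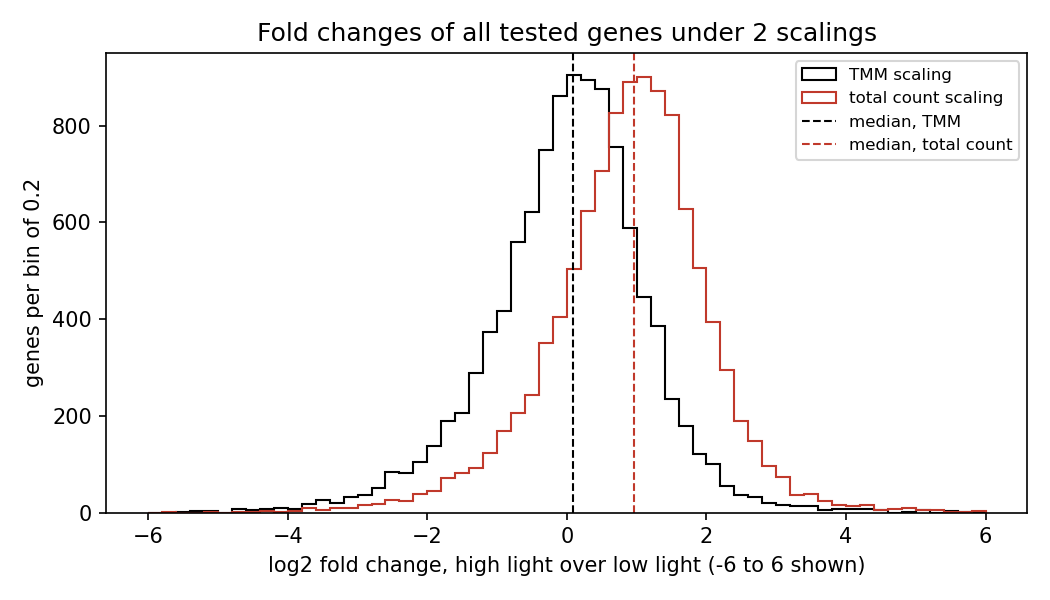
Distribution of log2 fold changes (high light over low light, x axis) over the 10629 tested genes, as genes per bin (y axis), with TMM scaling in black and total count scaling in red. Dashed lines mark the medians, 0.09 and 0.96 on the log2 scale, and the outlines have a similar shape at a different position.

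Among genes with a symbol, the 12 largest increases under the fixed rule belonged to MCM2, GAPDH_3, FAO1, PGK, HAD2, GapC4, Lhcr8, KCT3, ATPase1-P5, ATPase1-2B, DYN1 and RAD4. MCM2 rose from 5.90 ± 0.573 to 94.6 ± 22.5 CPM (mean ± SD, n = 3 cultures per group), a log2 fold change of 4.003 (SE 0.22; edgeR adjusted p = 7.72e-07). PGK rose from 23.0 ± 8.46 to 124.9 ± 6.58 CPM (log2 fold change 2.44, SE 0.25). GAPDH_3 and GapC4, both named for glyceraldehyde-3-phosphate dehydrogenase, were 6.06-fold and 4.10-fold higher. RAD4, named for a nucleotide excision repair protein, was 3.36-fold higher.

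Under the fixed rule, with its minimum of 10 CPM on average, the 12 largest decreases among genes with a symbol were in Lhcx1, Lhcf15, Lhcf5, DHLTA_4, ISIP3, SMP1, Tpt3, HSF2, SUMO, HemF_2, FABB and PPdK. Lhcx1 fell from 872.1 ± 176.8 CPM in LL to 26.8 ± 4.25 in HL (log2 fold change -5.02, SE 0.23; edgeR adjusted p = 4.88e-07). Lhcf5 was among the 5 most abundant transcripts in LL, at 13945 ± 1140.5 CPM, and had 692.9 ± 238.0 CPM in HL. SMP1 went from 8002 ± 907.4 to 828.1 ± 65.1 CPM. ISIP3, an iron starvation induced protein, was 9.997-fold lower, SUMO, a small protein modifier, 6.73-fold lower, and PPdK, pyruvate phosphate dikinase, 4.95-fold lower.

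**Figure D2:**
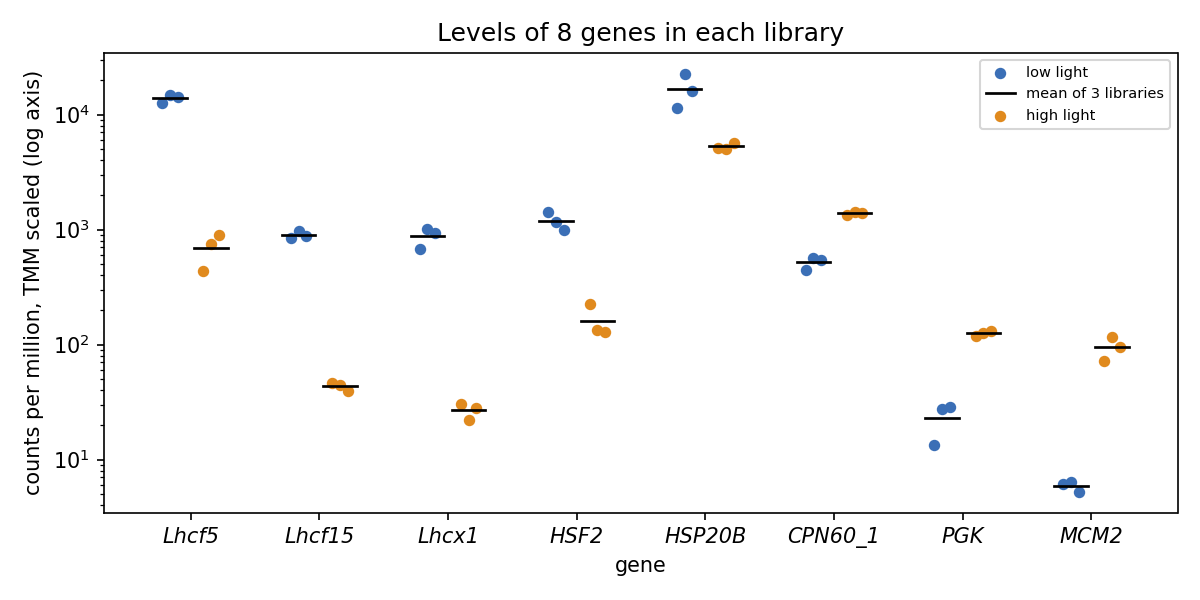
TMM-scaled CPM (log y axis) of 8 genes in each of the 3 low light libraries (blue) and 3 high light libraries (orange), with group means as black lines. Lhcf5, Lhcf15, Lhcx1, HSF2 and HSP20B were lower and CPN60_1, PGK and MCM2 higher in every high light library, and under total count scaling the group differences kept these directions.

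Under the rule that took genes whatever their name, the 3 largest decreases and 3 largest increases belonged to genes without a symbol. Phatr3_EG01529 fell from 499.6 ± 84.6 to 0.397 ± 0.284 CPM (log2 fold change -10.23, SE 0.36), Phatr3_J47715 was 229-fold lower and Phatr3_J43123 176.5-fold lower. Phatr3_Jdraft1239 had 1 count in the 3 LL libraries together and 992 in the HL libraries. Scaled by library totals and TMM factors this was a ratio of 543, with a 95% counting interval of 97.3 to 21484. Phatr3_J48827 and Phatr3_J45944 rose by log2 fold changes of 6.41 (SE 1.05) and 5.51 (SE 1.18), with wide spread: Phatr3_J45944 had 5198, 1267 and 966 CPM in the HL libraries and 0.897, 124.4 and 37.3 in LL. Leaving out single libraries gave log2 fold changes of 4.36 (without HL replicate 1) to 7.01 (without LL replicate 2) for Phatr3_J45944 and of 5.30 to 7.91 for Phatr3_J48827 in the same settings. The most abundant HL transcripts were Phatr3_J55230, HSP20B, Phatr3_J46448, HSP20 and HSP20A. In LL they were HSP20B, Phatr3_J45591, Phatr3_J49202, Lhcf5 and Phatr3_J44259. Of these, Phatr3_J45591 (10.9-fold lower in HL), Phatr3_J44259 (9.88-fold lower) and Phatr3_J49202 (4.07-fold lower) changed. Phatr3_J46448 (log2 fold change 0.31) and HSP20 (0.48) were not called under TMM and were higher under total count scaling. Phatr3_J55230 had a log2 fold change of -0.44, not called, and of 0.45 under total count scaling, also not called.

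Most antenna genes fell. Of 19 tested Lhcf and Lhcr genes, which encode the fucoxanthin-chlorophyll proteins that collect light, 15 fell, Lhcr8 rose (3.99-fold), and Lhcf3, Lhcf4 and Lhcf12 were not called; adjusted over the list alone the counts were also 15 and 1. Besides Lhcf5 and Lhcf15, members that fell included Lhcf8 (log2 fold change -1.65, SE 0.23), Lhcr12 (-1.36, SE 0.20) and Lhcf10 (-1.04, SE 0.17). It was the 1 list of 12 called by camera (adjusted p = 0.00093), with adjusted p = 0.943 with an estimated correlation, and under total count scaling 4 members were lower, 3 were higher and the median log2 fold change was -0.07 in place of -0.95. Most Lhcf and Lhcr genes lay above 200 CPM in LL. All genes above that level had a median ratio of HL over LL of 0.739 on total counts. Sorting genes by their LL level itself favours a low ratio at the top level, and no set matched on both groups was tested. Whether the camera call sets the list apart from abundant genes in general was therefore not settled. The other 11 lists were not called by camera, with an adjusted p of 0.385 or more. Of the genes of the stress-related Lhcx group, Lhcx1 and Lhcx4 (2.15-fold lower) fell, and Lhcx4 was not called under total count scaling. Lhcx3 had a log2 fold change of -0.11 (SE 0.18), not called, against 0.75 and called higher under total count scaling. Antenna genes form multigene families whose near-identical copies can share reads, and the values of single members are uncertain to that extent.

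**Figure D3:**
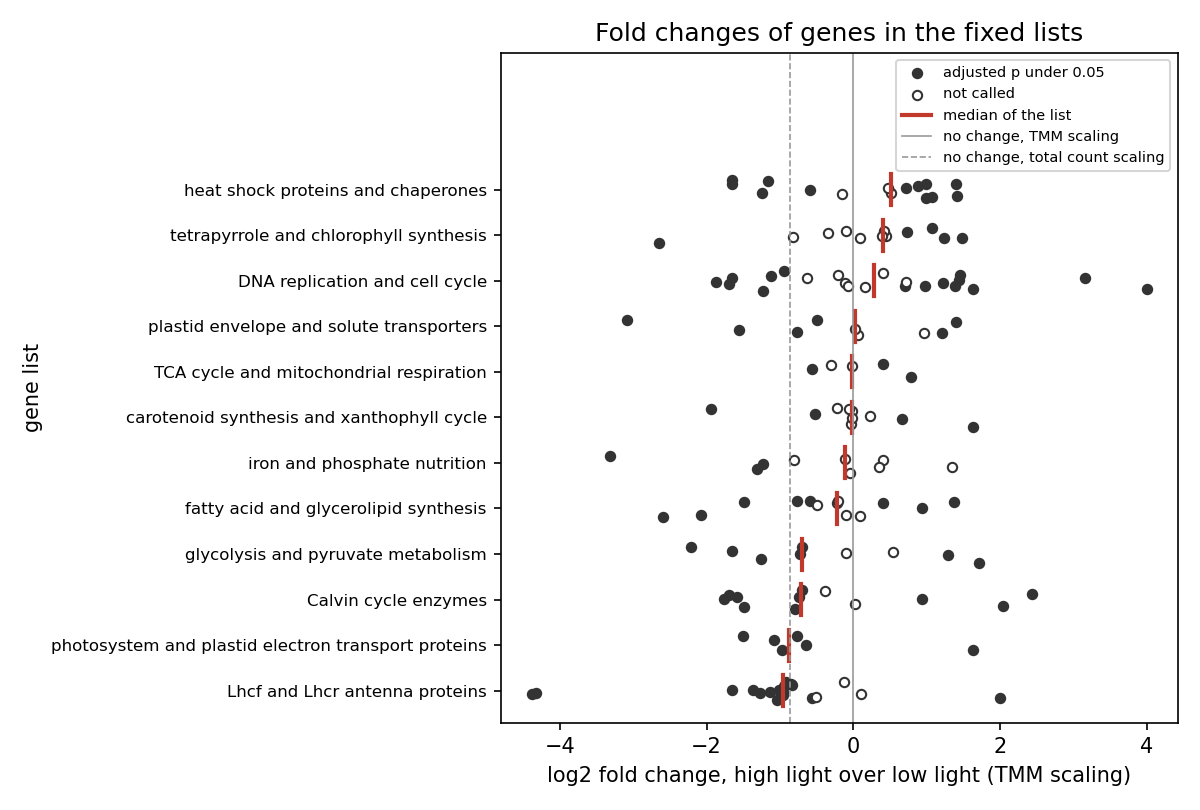
Log2 fold change of each tested gene (x axis, high light over low light, TMM scaling) in the 12 fixed lists with at least 5 tested members (y axis), filled where the adjusted p was under 0.05, with list medians in red. The solid line marks no change under TMM and the dashed line no change under total count scaling, and the median of the Lhcf and Lhcr list (-0.95) lies beside the dashed line.

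Of 6 genes in the photosystem and plastid electron transport list 5 fell, although camera did not call the list (adjusted p = 0.385, or adjusted p = 0.943 with an estimated correlation). They were PsbM (2.85-fold), PetJ, a cytochrome c6 (2.11-fold), PsbO of the oxygen-evolving complex, petC and AtpC, but with total counts 1 member was called lower and 1 higher, and AtpC and petC turned to 0.23 and 0.10 on the log2 scale. The 1 member that rose, PSAT (3.09-fold), carries a symbol used for phosphoserine aminotransferase, not for a photosystem subunit. In tetrapyrrole and chlorophyll synthesis 4 of 12 genes rose, chlM (2.78-fold), HemF_1 (2.36-fold), HemE_1 and HemE_2, while HemF_2, named like HemF_1 for coproporphyrinogen oxidase, was 6.25-fold lower and 7 were not called. With total counts 10 tetrapyrrole genes were higher and 1 lower. Carotenoid and xanthophyll cycle genes went both ways, with CRTISO2 (3.09-fold) and ZEP1, a zeaxanthin epoxidase (1.59-fold), higher, PDS2, named for phytoene desaturase (3.82-fold), and CRTISO3 lower, and 6 of 10 not called; with total counts 8 were higher, 1 was lower, and CRTISO3 turned to 0.34. DXS, the single isoprenoid gene matched by symbol, fell (log2 fold change -0.76), against 0.11 under total count scaling. Adjusted over the list alone, the counts of these lists were unchanged.

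Genes of carbon metabolism went both ways. The Calvin cycle list was matched by symbol alone, so its 12 genes can include forms of these enzymes that act outside the plastid. Of these 12 genes 7 fell, including Rpe (3.38-fold lower), Fba4 and GapC2a, and PGK, GapC4 and Fba3 rose. With total counts 4 were lower and 4 higher. In glycolysis and pyruvate metabolism PYC1, a pyruvate carboxylase (4.64-fold), and the pyruvate kinase PK1 (3.16-fold) were among 5 of 9 genes that fell, while PK4a (3.30-fold) and PDHB1 rose. Adjusted over the list alone 5 glycolysis genes fell and 3 rose, and with total counts 2 were lower and 4 higher. Of 5 genes of the tricarboxylic acid cycle and respiration, Fum (1.72-fold) and FUM1 (1.32-fold), both named for fumarase, rose and the alternative oxidase AOX1 (1.48-fold) fell; AOX1 had a log2 fold change of 0.30, not called, under total count scaling, and FUM1 (edgeR adjusted p = 0.046) lost its call when any single library other than LL replicate 1 was left out. With total counts 4 of these genes were higher and 0 lower. The list's median log2 fold change was -0.01 and its mean 0.06, with camera's direction upward, and the median was 0.85 with total counts. In fatty acid and glycerolipid synthesis 5 of 13 genes fell, including FABB (6.07-fold), FABFa (4.22-fold) and FABD (2.81-fold), and 3 rose; adjusted over the list alone 6 fell and 3 rose, and with total counts 3 were lower and 7 higher. Of the bicarbonate transporter genes SLC4A_1 fell and SLC4A_2 rose under both scalings. Of the nitrogen assimilation genes GltD and GLNA rose and GltX fell, with GltX at 0.49 and called higher under total count scaling.

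Transport and nutrient genes also differed by member. Of 9 plastid envelope transporter genes 4 fell, Tpt3, NTT6 (2.96-fold), Tpt1 and TPT2, and NTT1 (2.65-fold) and NTT3 rose; adjusted over the list alone 4 fell and 3 rose, and with total counts 2 were lower and 6 higher, Tpt1 and TPT2 turning to 0.11 and 0.38. The list's median log2 fold change was 0.03 and its mean -0.25, with camera's direction downward. Of 9 iron and phosphate nutrition genes ISIP3, FRE5 (2.49-fold) and FRE4 (2.35-fold) fell and 6 were not called; adjusted over the list alone the count was also 3, and with total counts 2 were lower and 5 higher. FRE4 lost its call in 3 settings, under total count scaling and without LL replicate 1 or 2.

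Chaperone genes went both ways. Of 15 genes 7 rose, among them CPN60_1, Hsp70_1 (log2 fold change 1.07, SE 0.19), HSP90 (0.99, SE 0.18) and HSP40C (1.40, SE 0.17), and 5 fell, among them the small heat shock genes HSP20A (3.15-fold), HSP20B (3.15-fold) and HSP20C; adjusted over the list alone the counts were also 7 and 5. With total counts 9 were higher and 3 lower, and HSP70F turned from -0.58 to 0.29. CPNE1b, 1 of the 7 that rose, carries a symbol of the copines, which are not chaperones. All 3 tested genes of the transcription factor list were heat shock factors, and HSF2 fell from 1197 ± 212.0 to 161.8 ± 54.8 CPM (log2 fold change -2.89, SE 0.26), HSF1 by 1.92 and HSF3 by 1.82 on the log2 scale.

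In DNA replication and the cell cycle 9 of 22 tested genes rose and 6 fell, and adjusted over the list alone the counts were the same. MCM2, MCM5, MCM7 and PCNA, the sliding clamp of DNA polymerase (log2 fold change 1.44, SE 0.22), rose, whereas MCM3, MCM4 and MCM6 had log2 fold changes of 0.72, -0.11 and -0.63 that were not called. CYCB2 was 8.91-fold higher at low level, with 3.14 CPM in HL and 0.333 in LL. CDKA1, a cyclin-dependent kinase, fell 3.67-fold from 279.6 ± 17.1 to 76.2 ± 6.23 CPM. With total counts 15 of these genes were higher and 3 lower. The histone H3.3 gene fell by 0.82 on the log2 scale and stood at 0.05 with total counts.

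Of the photoreceptors, CPF1, a cryptochrome/photolyase family member, fell 3.25-fold and CPF2, of the same family, was 2.02-fold higher, both called under both scalings. The phytochrome gene Dph1 had a log2 fold change of 0.29 (SE 0.22), not called, and was called higher under total count scaling (1.15) and without LL replicate 1 (0.59). CDPK1 fell by 0.82 on the log2 scale, against 0.04 with total counts, and the calmodulin genes CaM1 and CaM2 were not called. UBC2 rose and UBC1 fell by 0.46, although UBC1 stood at 0.41 with total counts, and TufA, an elongation factor, rose (log2 fold change 0.41). The 4 ribosomal protein genes and the 4 antioxidant genes SOD1, SOD2, APX1 and Trx-y that were matched by symbol were not called. Their list medians were 0.16 and -0.02, and with total counts 4 and 3 of them were called higher. Genes of these classes without a symbol were not covered. Adjusted over the list alone, the counts of these small lists were unchanged, and lists with fewer than 5 tested members had no list test.

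No pair of libraries of a group was close enough to be 1 library counted again, and in each group replicate 1 was farther from the other libraries than these were from each other. Chi-square per degree of freedom was 39.8 and 36.7 between LL replicate 1 and the other LL libraries, against 11.25 between those, and 34.7 and 42.8 against 6.60 in HL. With both replicate 1 libraries left out, a setting chosen after seeing the data, 3815 genes were higher and 3468 lower.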

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

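Leaving out both replicate 1 libraries, and leaving PSAT and CPNE1b out of their lists, were chosen after the results were seen. Total count scaling moved the gene counts most, to 7233 higher, 1130 lower and 5699 changed at least 2-fold. That follows from its construction, which leaves out the 0.87 shift on the log2 scale between the groups; why the groups differ so was not settled. In the other settings each of the 3 counts stayed within 1.5 times its main value. Leaving out single libraries gave 2733 to 3448 genes higher and 2667 to 3201 lower, DESeq2 gave 2948 and 3144, and leaving out both replicate 1 libraries gave 3815 and 3468. Camera called 1 list in each setting with the preset correlation. With an estimated correlation it called 0, and 0 lists had an unadjusted p under 0.05. Fry, run with TMM scaling only, called 3 lists, Lhcf and Lhcr antenna proteins, iron and phosphate nutrition and fatty acid synthesis. It called all 12 when changes in either direction were tested. Fry asks whether the members of a list changed, not whether the list differs from other genes. With 59.0% of all tested genes called, the 12 calls do not set any list apart.

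Of 67 named genes, 57 kept direction and call in every setting run. Reversed log2 fold changes occurred under total count scaling for AOX1 (0.30), Lhcx3 (0.75) and Phatr3_J55230 (0.45), and for Lhcx3 without LL replicate 1 (0.038, with a range of -0.21 to 0.038 over single libraries left out) and with both replicate 1 libraries left out (0.096); Lhcx3 was not called in the main test, and beyond the shift the cause was not tested. PetJ, FRE4 and Lhcx4 lost their calls under total count scaling, and FRE4 without LL replicate 1 or 2. FUM1 lost its call in 9 settings. Thinning each library to the smallest total gave 3267 genes higher and 2984 lower. Counting error limits Phatr3_Jdraft1239, whose ratio rests on 1 LL count (97.3 to 21484). Libraries with the same number did not deviate together, with correlations of their deviations of -0.0499, -0.0631 and 0.111, and not every library correlated best with its own number. A replicate block gave 3136 genes higher, 2920 lower and 3334 changed at least 2-fold, and 1 list.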

Other observations

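Genes were also grouped into 26 families by symbol, after the data were seen; some of these families overlap the fixed lists, and none outside them passed its test. All 4 tested genes of replication factor C, which loads the sliding clamp, were higher in HL, from RFC3 (log2 fold change 0.42, SE 0.16) to RFC4 (1.22, SE 0.18). Of 7 genes named for the anaphase promoting complex, a ubiquitin ligase of mitosis, 5 were higher, including APC7 (1.88, SE 0.48), and APC8 was lower (-1.62, SE 0.19). Of 11 diatom-specific cyclin genes 2 were higher and 5 lower, among them dsCYC2 (-2.88, SE 0.45, at 0.252 CPM in HL and 1.92 in LL), and the family median of -0.50 became 0.36 with total counts. Of 8 genes of the proteasome regulatory particle (RPN) 1 was lower, and of 11 histone genes 1 was higher and 1 lower; with total counts the family medians went from -0.17 to 0.70 and from -0.08 to 0.78, and the lower genes RPN2 and H3.3 stood at 0.34 and 0.05. Camera called 1 of the 26 families, Lhcf, which is part of the fixed antenna list (adjusted p = 0.0024), with adjusted p = 0.929 with an estimated correlation. The replication factor C (camera adjusted p = 0.253) and anaphase promoting complex (0.395) families failed the correction.

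Log2 fold changes of neighbouring genes in the reference order had a Spearman correlation of 0.172 over 7621 pairs, of 0.0629 at 2 places apart and of 0.0307 at 5, across genes, which are not independent replicates. Permutation p-values were 0.001, 0.001 and 0.007 over 1000 permutations, of which 0.001 is the smallest they can give.

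The 3 patterns below were picked after looking at the data. The tests of the 100 most abundant genes, of genes at 0.5 to 2 CPM, of the rise by level, of the share over all genes with a count, of carried-over reads, of the summed Lhcx level, of scaling and of exchanged labels were chosen only after the result was seen. The test of tested genes below 1.75 CPM, the test without HL replicate 1 and the splits of the libraries were set beforehand.

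Most genes took a larger share of the reads in HL, with a median log2 ratio of 0.92 before TMM scaling, and CPM in this paragraph are on total counts. With the 100 most abundant genes out of the totals the ratio was still 0.72 (0.60 to 0.86 over pairs of an HL and an LL library), which argues against those genes as the whole cause, and with 1000 and 2000 genes out it was 0.44 (0.33 to 0.53) and 0.36 (0.25 to 0.42), so abundant genes hold part of the shift. An even background of genomic DNA in HL went with the test set beforehand, since 0.696% of tested genes (74 of 10629, 95% interval 0.547 to 0.873) lay below 1.75 CPM in HL, under the limit of 1%, but the low count filter set that outcome: over all 11401 genes with a count the share was 7.17% (817 genes). The tests added because of that outcome argue against a background equal for all genes as the whole cause. Genes at 0.5 to 2 CPM in LL had a median of 4.44 CPM in HL (4.09 to 4.66) against a required 8.735. The median rise was 3.14 CPM for these, 7.23 (6.79 to 7.56) for genes at 2 to 5 CPM in LL and 13.6 at 5 to 20. It was 22.5 (21.1 to 23.5) at 20 to 50 and, no longer larger, 21.7 (18.4 to 24.5) at 50 to 200. Genes above 200 CPM in LL went the other way, with a median change of -102.7 CPM and a median ratio of HL over LL of 0.739. The intervals of these medians come from resampling genes within a level and leave out the variation among cultures. A smaller background, or one in proportion to gene length, which was not used here, stays open, as does a broad change of the transcriptome with light, which is untested.

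Phatr3_J45944 and Phatr3_J48827 varied together between libraries, with 52141 and 17773 counts in HL replicate 1, 725 and 136 in LL replicate 2, and 5 and 0 in LL replicate 1. Reads carried over from HL libraries would bring the HL ratio of the genes, 2.76 to 2.93, but the ratio in LL replicate 2 was 5.33 (4.43 to 6.45). HL replicate 1 alone did not account for the rise, since without it the smaller log2 fold change was 4.36 and both genes were called. A shared response to light that differs in strength between cultures may be involved, which is a hypothesis these tests did not address, and reads shared with other copies were not tested.

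Lhcx1 was 32.5-fold lower in HL. The summed level of Lhcx1, Lhcx3 and Lhcx4 was 15.4 times higher in LL (924.3 against 60.2 CPM), which argues against reads moved among these 3 genes, although Lhcx2 was not matched and stays open. Under total count scaling the log2 fold change was -4.15, so scaling does not account for it. An exchange of the group labels would make Lhcf and Lhcr genes, known to be lowered by strong light, higher in HL than other genes. Instead 15 of 16 called members were lower under TMM. In 9 of 9 pairs of an HL and an LL library the list's median log2 ratio lay below that of all tested genes. The pairs reuse the same 6 libraries and are not independent. The difference was -0.46 to -1.38 (middle value -1.02), whatever the scaling. These values do not decide on an exchange, because most of the list was abundant in LL and no set of like level was compared. Genes above 200 CPM in LL had a median ratio of HL over LL of 0.739 on total counts. Sorting by LL level itself favours a low ratio there, so it cannot tell how far abundance alone lowers the list. The 57.1% (4 of 7) called lower with total counts decides nothing, since that scaling raises all genes alike, and a true response of Lhcx1 to light stays open as an untested hypothesis.

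The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3285 genes higher, 2986 lower and 3367 changed at least 2-fold (edgeR). The highest of the other splits gave 0 for each, with at most 283 genes at an unadjusted edgeR p under 0.05. So 1 split reached each count. Every other split put HL and LL libraries together in both of its groups. The light difference then adds to the spread within groups and hides calls, so these 0 counts do not stand for chance alone. For gene lists called by camera, 6 of the 10 splits reached the real value of 1, and the highest other gave 6.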
